A study of Mus musculus with 6 samples.

How the data were processed

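Liver RNA of 6 male mice was sequenced, 3 Slc7a11-LTG transgenic mice (TG) and 3 control mice (WT). All were 8 weeks old and had been fed an MCD diet, which lacks methionine and choline, for 1 week. The 6 samples hold no group on another diet. Per the labels' protocols, livers were frozen on dry ice, RNA was taken up in Trizol, and libraries were made with the VAHTS Universal V6 kit. The labels' molecule and library source fields name genomic DNA, although the protocols describe RNA; the values were treated as RNA counts. The submitters' processing notes name TopHat, Cufflinks and the mouse genome build mm10, without versions. The counting program, its annotation, its handling of reads with several matches and its strand setting are not given in the sources used here.

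The deposited table holds whole-number read counts per Ensembl gene, not normalized, for 52550 gene identifiers in each of the 6 libraries. Every column of the table belonged to 1 of the 6 samples. Symbols were taken from a gene name table of the reference, which matched 52403 identifiers and left 147 without a symbol. These 147 held at most 0.0034% of a library's counts. Coordinates came from the GENCODE annotation of the same mouse build. Total counts lay between 16016640 and 17463329 per library. At this depth, 3 counts, taken as the smallest number that can be told from 0, correspond to 0.172 to 0.187 CPM, the usual unit for counts scaled to a common library size. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules.

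Genes with too few counts were removed with filterByExpr of edgeR by group, which left 14031 genes. TG and WT were compared with edgeR's quasi-likelihood test (version 4.0.16, TMM scaling, robust dispersion, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are TG minus WT with standard errors (SE), computed as the fold change over the root of the test's F value. CPM are TMM-scaled and are given as mean ± SD with n = 3 mice per group. The common biological coefficient of variation was 0.329, and the median prior degrees of freedom were 3.47. The labels state no shared litter, cage or day between groups, so the replicate number was not a term of the model. The replicates are separate mice according to the series' design text. An exact two-sided permutation test of 3 against 3 mice cannot give a p below 0.1, so none is reported.

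The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. A total of 47 gene lists covered pathways of glutathione, amino acid, lipid, bile acid and energy metabolism, stress and inflammatory responses, matrix, and markers of the cell types a liver sample can hold. Lists with at least 5 tested members, 45 in all, were tested with limma's camera (version 3.58.1) on voom values, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera asks whether the members of a list rank higher or lower than other genes. Fry, run beside it, asks whether the members move on balance in one direction or, in its mixed form, in either; it does not compare a list with other genes. Members were also counted after adjustment of the edgeR p-values over all genes and over the list alone.

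Genes were named by a fixed rule. It took Slc7a11; up to 10 genes with the largest change in each direction among those past the threshold, which took no gene. It also took the 10 smallest unadjusted p among genes with a symbol and a mean of at least 1 CPM, up to 4 members with the smallest p of each list past the camera threshold; and a set of genes tied to the transgene, to ferroptosis, mitophagy, fibrosis and inflammation. Some genes that the rule took are not reported here. Any other gene is said to have been chosen after its values were seen.

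The edgeR, DESeq2 (version 1.42.0) and voom fits were tested on counts simulated from the means and library sizes of these 6 libraries, with 200 changed genes among 13787. EdgeR called 10% of the genes changed 2-fold, 68% of those changed 4-fold, 86% of those changed 8-fold, and 7 of 13587 unchanged genes. DESeq2 called 30%, 76% and 96% of them, and 45 unchanged genes. Of 50 genes changed 512-fold, edgeR and DESeq2 called 100%. DESeq2 thus called 15, 38, 48 and 50 changed genes beside 45 unchanged ones, a larger false share than its threshold allows. Its calls in the livers are to be read with that limit. Slc7a11, 512-fold higher in TG livers, had an adjusted p of 0.164 with edgeR's quasi-likelihood test. The simulated shares therefore cannot be taken as the power in these livers. For a simulated list of 30 genes shifted by 0.5 on the log2 scale, camera gave an adjusted p of 8.67e-06 with the preset correlation and 0.175 with an estimated one, and fry gave 0.000592. The simulated genes were drawn independently of each other. The simulation therefore cannot show which setting holds for liver genes that vary together.

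Alternatives were DESeq2 and limma voom, other scalings (size factors of DESeq2, upper quartile, library size only), other filters on low counts, robust dispersion switched off, a fold threshold of 1.2, an adjusted p of 0.1, the replicate number as a block, leaving out the 10 genes of highest count, and leaving out each library in turn. Leaving out replicate 3 of both groups, other scalings for the lists, and the alternatives for members counted over a list alone were added after the data were seen. Lists were also tested with an estimated correlation, with fry, under another filter and without Slc7a11. Sets of near-identical genes (immunoglobulin, serum amyloid, orosomucoid and cytochrome P450 families, ribosomal proteins with pseudogenes, and mitochondrial genes with nuclear copies) share reads that the counting could have split or dropped, so values of single members are uncertain. Genes that overlap another gene on either strand are uncertain for the same reason.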

Results

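The data were read counts per gene from the livers of 3 Slc7a11-LTG transgenic mice (TG) and 3 control mice (WT), all male, 8 weeks old and fed a methionine- and choline-deficient diet for 1 week. The labels imply 1 comparison, the liver transcriptome of TG against WT mice on this diet. Total counts were 16882477, 17463329 and 17120294 in TG replicates 1 to 3 and 16844376, 16016640 and 17021394 in WT replicates 1 to 3. Between 19004 and 20732 genes had at least 1 count in a library.

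Slc7a11, which encodes the cystine-glutamate exchanger subunit xCT, was the most clearly separated gene. It is annotated on chromosome 3 from 49892526 to 50443614 on the minus strand (ENSMUSG00000027737, build mm10). TG replicates 1 to 3 held 72729, 24359 and 57242 counts, and WT replicates 1 to 3 held 46, 44 and 204. The mean was 2900 ± 1520 CPM in TG and 5.62 ± 4.33 CPM in WT livers (SD, n = 3 each), a log2 fold change of 9.0 with an SE of 0.87. Counts per gene do not show which exons were read or whether a transcript came from the transgene. The adjusted p was 0.164 with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 3.19e-51 with DESeq2 and 0.0183 with limma voom. Without TG replicate 3, edgeR's adjusted p was 0.0207, and over the libraries left out in turn it lay between 0.0207 and 0.697. The range over all alternatives was 3.19e-51 to 0.697.

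**Figure D1:**
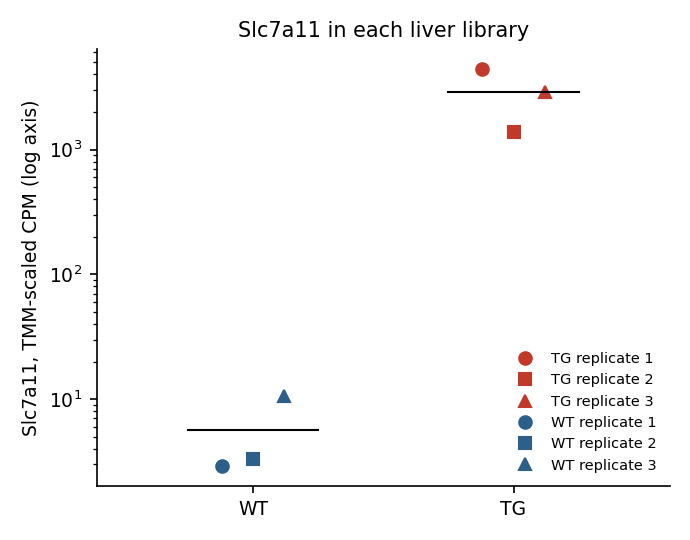
Slc7a11 in TMM-scaled CPM (log axis) in the 3 WT and 3 TG livers, with 1 symbol per replicate and the group mean as a line. The TG livers lie between 1377 and 4416 CPM and the WT livers between 2.92 and 10.6 CPM.

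TG replicates 1 and 2 lay apart from the WT livers on the first principal component, and TG replicate 3 lay between. On this component, which took 43.3% of the variance, TG replicates 1 to 3 lay at -37.1, -66.8 and 2.9, and WT replicates 1 to 3 at 29.9, 60.1 and 10.9. The closest pair of libraries by log2 CPM was TG replicate 3 and WT replicate 3 (Pearson r = 0.973 across genes, which are not independent replicates). TG replicate 1 was closest to TG replicate 2 (0.967). Its r with WT replicate 1 (0.945) exceeded that between WT replicates 1 and 3 (0.941), so the groups were not apart by this measure. No pair agreed within sampling noise.

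**Figure D2:**
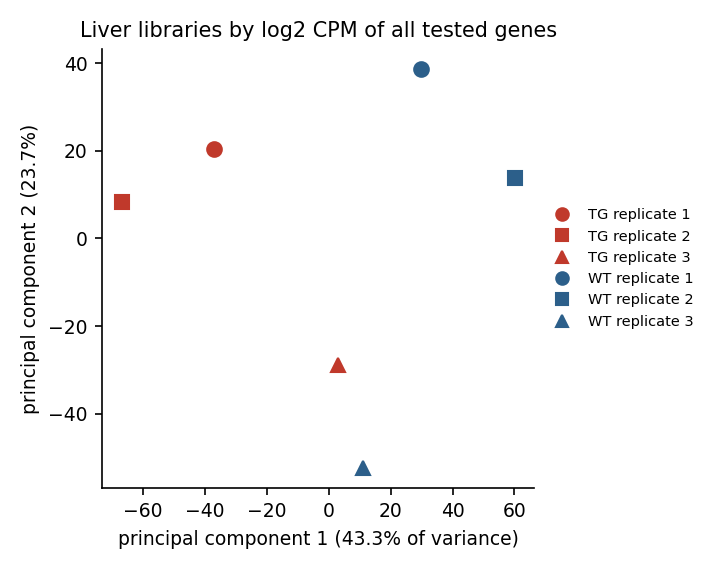
Principal components 1 (43.3% of variance) and 2 (23.7%) of log2 CPM over 14031 genes, with 1 symbol per liver library. TG replicate 3 and WT replicate 3 are the lowest points on component 2, at -28.9 and -52.3.

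EdgeR's quasi-likelihood test called 0 of 14031 genes at an adjusted p of 0.05. At an unadjusted p below 0.05 it gave 1551 genes, 1218 higher and 333 lower in TG, where chance alone gives about 702. DESeq2 called 390 genes, 354 higher and 36 lower, and limma voom called 1, Slc7a11. The 3 TG values lay all above or all below the 3 WT values for 2155 genes, 15.4% against an expected 10% by chance. Genes vary together, so a single grouping can lie far from either expectation, and the excess over it was not tested. With edgeR, other splits of the 6 libraries into equal groups gave 169 to 1592 genes at an unadjusted p below 0.05. Without TG replicate 3, edgeR called 305 genes, 288 higher and 17 lower, and 215 of these were among the 390 of DESeq2. The number at an unadjusted p below 0.05 was 759 without TG replicate 2 and 2328 without WT replicate 3. Of the 1551 genes, 78.5% were higher in TG with TMM scaling and 93.3% of 1410 with library size only, a scaling that moved the median of all genes by 0.12 on the log2 scale.

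The genes with the smallest unadjusted p beside Slc7a11 included Cd9, a tetraspanin, at 43.1 ± 4.76 CPM in TG against 17.47 ± 2.44 in WT. Uap1l1 lay at 45.7 ± 2.45 against 20.3 ± 3.28 CPM and Rragd, a GTPase of the lysosomal amino acid sensing complex, at 9.56 ± 1.39 against 3.48 ± 0.220 CPM. Low-abundance genes among them were Arhgap22 (log2 fold change 3.44, SE 0.53), Ahnak2 (3.28, SE 0.53), Basp1 (2.45, SE 0.41) and Pik3r6 (2.62, SE 0.45). Col5a3, a fibrillar collagen, was 1.84-fold higher at 37.7 ± 1.53 against 20.5 ± 2.34 CPM. G6pc, the glucose-6-phosphatase that releases glucose from liver, lay at 244 ± 26.1 CPM in TG and 715 ± 108 in WT. In each of these 9 genes all 3 TG livers lay beyond all 3 WT livers. Their adjusted p was 0.343 with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, and between 1.26e-10 and 0.00305 with DESeq2.

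Markers of Kupffer cells and other macrophages were higher in TG livers, with a median log2 fold change of 1.91. All 32 tested members had a positive fold change. Cd68, a lysosomal glycoprotein of macrophages, was 3.41-fold higher (39.5 ± 13.1 against 11.6 ± 2.99 CPM), and Gpnmb, a glycoprotein of lipid-laden macrophages, 5.45-fold higher (22.7 ± 3.50 against 4.10 ± 3.65 CPM). Cd63, a tetraspanin of late endosomes, was 2.42-fold higher. Adgre1, which encodes F4/80, lay at 82.3, 163 and 20.6 CPM in TG replicates 1 to 3 and at 15.8, 10.3 and 28.1 CPM in WT replicates 1 to 3. With edgeR, 28 members rose when adjusted over the list alone and 0 when adjusted over all genes; DESeq2 called 22 over all genes. Camera placed the list higher in TG with an adjusted p of 2.3e-18 with the preset correlation. The adjusted p was 0.56 with an estimated correlation. The median of the list against the WT mean was 1.95, 2.68 and 0.38 in TG replicates 1 to 3 and -0.09, -0.38 and 0.40 in WT replicates 1 to 3. The 28 members became 2 without TG replicate 2, 2 without WT replicate 1 and 1 without WT replicate 2.

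Several inflammatory genes were highest in TG replicates 1 and 2. Saa1, an acute phase protein, lay at 343, 2701 and 31.4 CPM in TG replicates 1 to 3 and at 12.4 to 16.4 CPM in WT livers. Orm2 lay at 376, 1876 and 19.96 CPM against 11.04 to 19.56 in WT, and Lcn2 at 380, 2934 and 56.2 CPM against 13.5 to 69.1. The neutrophil genes S100a8 and S100a9 had log2 fold changes of 4.77 (SE 1.54) and 4.89 (SE 1.33), and TG replicate 3 lay at 0.102 and 0.711 CPM, within the WT range for the latter. Saa1, Orm2 and the immunoglobulin genes have near-identical copies, so their single values are uncertain. Ighg1, an immunoglobulin heavy chain, was at 90.1, 57.2 and 3.81 CPM in TG replicates 1 to 3 and 1.30 to 2.19 CPM in WT. Among cytokines, Il1b lay at 33.3 ± 22.9 CPM in TG against 5.52 ± 2.00 in WT, and Il1a at 8.74 ± 2.06 against 3.54 ± 0.802. Lgals3, which encodes galectin 3, was 4.28-fold higher, with its highest value in TG replicate 3 (59.9, 55.3 and 69.3 CPM).

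By list, the median log2 fold change was 1.03 for 28 acute phase genes, 2.32 for 8 neutrophil markers, 1.07 for 16 B and plasma cell markers and 0.90 for 31 cytokine and chemokine genes. In TG replicate 3 the medians against the WT mean were -0.1, -0.33, 0.2 and 0.28, each within the range of the WT livers. They were 0.76, 2.36, 1.17 and 1.21 in TG replicate 1 and 1.9, 3.13, 1.55 and 1.52 in TG replicate 2. Adjusted over the list alone with edgeR, 0, 5, 3 and 4 members of these lists rose, and 0 of each did over all genes. DESeq2 called 5, 3, 4 and 5 of them over all genes, and 12 acute phase genes were higher at an unadjusted p below 0.05. The 5 neutrophil members were Csf3r, S100a9, Lcn2, S100a8 and, named after its values were seen, Mmp9; the 3 plasma cell members were Ighg1, Igkc and Ighg2b. Camera's adjusted p was 1.2e-06, 0.017, 0.003 and 1.5e-09. It was 0.59, 0.59, 0.56 and 0.56 with an estimated correlation. When adjusted over the list alone, 16, 13, 9 and 16 members rose without TG replicate 3, with more neutrophil genes past the filter on low counts. Without TG replicate 2, WT replicate 1 or WT replicate 2, 0 members of the 4 lists did. Without TG replicate 1 the numbers were 0, 3, 0 and 0, and without WT replicate 3 they were 0, 0, 0 and 12. Over the alternatives that keep all libraries, the numbers ranged from 0 to 12, 0 to 12, 0 to 8 and 1 to 12, with the lowest of each in voom. With no filter on low counts, 0 neutrophil and 1 plasma cell members rose. Library size only gave 3 acute phase and 8 plasma cell members, upper quartile scaling 8 plasma cell members, and a mean of at least 1 CPM 8 plasma cell and 12 neutrophil members, with a neutrophil median of 4.77. The neutrophil list's camera call ended without TG replicate 1 (adjusted p 0.069) and without WT replicate 3 (0.055).

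Matrix genes were higher in all 3 TG livers. The list of fibrosis and extracellular matrix genes had a median log2 fold change of 0.87 and 44 of 45 members above 0. Its median against the WT mean was 1.12, 0.89 and 0.68 in TG replicates 1 to 3 and 0.22, -0.40 and 0.21 in WT replicates 1 to 3. Thbs1, a matrix glycoprotein, lay at 18.8 ± 4.74 CPM in TG and 3.68 ± 2.60 in WT, Col1a2 at 21.4 ± 4.08 against 9.80 ± 3.24 and Tgfb3 at 2.79 ± 0.815 against 0.811 ± 0.208. Col1a1 lay at 12.4 ± 1.12 against 4.11 ± 2.69 CPM and did not pass when adjusted over the list alone, nor did Acta2, a marker of activated stellate cells (2.73 ± 1.68 against 1.89 ± 0.566). With edgeR, 9 members rose when adjusted over the list alone, Tgfb1 among them, and 0 over all genes; DESeq2 called 9 over all genes. Camera's adjusted p was 1.6e-16 with the preset correlation. It was 0.56 with an estimated correlation. The 9 became 0 without TG replicate 1, TG replicate 2 or WT replicate 1, 1 without WT replicate 2 and 16 without WT replicate 3. Macrophage markers, which were also higher, shared 1 gene with this list, Mmp12, named after its values were seen. Markers of stellate cells and fibroblasts had a median of 0.28 over 27 genes, with 0 past the threshold when adjusted over the list alone or over all genes, 6 at an unadjusted p below 0.05 and 1 called by DESeq2 (camera adjusted p 0.00058). That list's adjusted p was 0.56 with an estimated correlation. Without WT replicate 3, 3 of its members rose when adjusted over the list alone. The stellate and matrix lists shared genes, Col1a1, Col1a2 and Acta2 among them, so they are not separate evidence. Col1a2 was the 1 stellate and fibroblast marker that DESeq2 called.

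**Figure D3:**
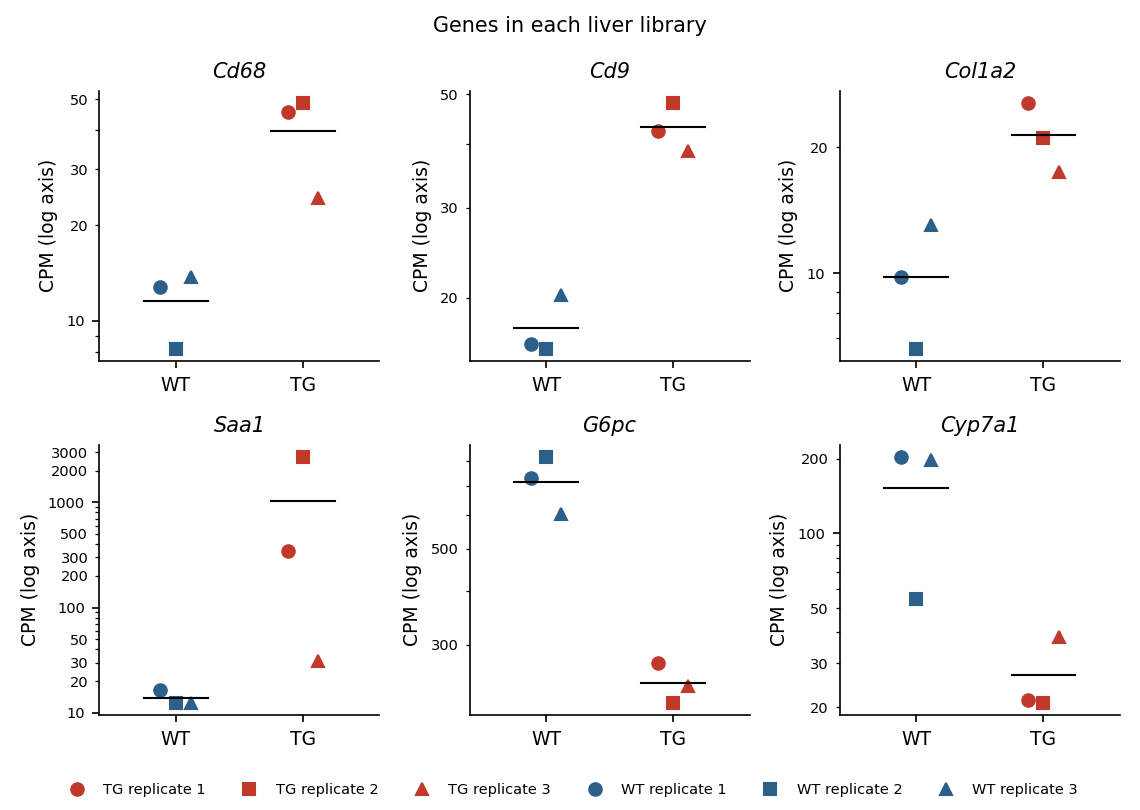
TMM-scaled CPM (log axes) of Cd68, Cd9, Col1a2, Saa1, G6pc and Cyp7a1 in each of the 3 WT and 3 TG livers, with 1 symbol per replicate and the group mean as a line. Saa1 in TG replicate 3 is at 31.4 CPM, against 343 and 2701 CPM in TG replicates 1 and 2, while G6pc lies between 220 and 272 CPM in all 3 TG livers.

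G6pc and Cyp7a1 were lower in TG livers, while most members of their lists did not pass the test. G6pc fell 2.93-fold and Pfkfb1, a regulator of glycolysis named after its values were seen, lay at 29 ± 3.6 CPM against 48.4 ± 5.16. These were the 2 of 30 gluconeogenesis and glycolysis genes that fell when adjusted over the list alone with edgeR; 0 did over all genes, and DESeq2 called 2 lower and 2 higher. The list was not called by camera (adjusted p 0.31). Over the libraries left out in turn, between 0 (without TG replicate 1) and 2 genes fell; it was 1 without TG replicate 3, WT replicate 1 or WT replicate 3, and without TG replicate 3, 3 other genes rose. The number that fell was also 1 with library size only and with a fold threshold of 1.2. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, lay at 26.8 ± 9.91 CPM in TG and 152 ± 84.5 in WT. It was the 1 of 25 bile acid genes that fell when adjusted over the list alone, 0 did over all genes, and DESeq2 called 1. This call ended without TG replicate 1, TG replicate 2, WT replicate 1 or WT replicate 3, each of which left 0, and also with voom, with upper quartile scaling, with library size only, with no filter on low counts and at a mean of at least 1 CPM. The bile acid list had a median of -0.34 (camera adjusted p 0.0018). It was 0.56 with an estimated correlation.

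Several cytochrome P450 genes of drug metabolism and several clock genes were lowest in TG replicates 1 and 2. Cyp2c37 lay at 33.6, 13.3 and 81.2 CPM in TG replicates 1 to 3 and at 300, 649 and 101 CPM in WT replicates 1 to 3, and Cyp2c50 at 141 ± 74.8 CPM in TG against 404 ± 162 in WT. Both belong to a family of near-identical genes and are uncertain as single values. The 27 P450 genes had a median of -0.74, and by library the median against the WT mean was -0.64, -1.15 and -0.14 in TG replicates 1 to 3 and -0.14, 0.34 and -0.29 in WT replicates 1 to 3. Of the clock genes, Hlf lay at 40.1 ± 9.39 CPM against 74.4 ± 14.6 and Tef at 116 ± 58.9 against 275 ± 93.5, and the list's median over 22 genes was -0.55. Of these, 6 were above 0, and Arntl, a core clock activator named after its values were seen, lay at 20.2, 17.0 and 2.13 CPM in TG replicates 1 to 3 and at 11.5, 1.06 and 1.66 CPM in WT replicates 1 to 3. With edgeR, 0 members of either list passed when adjusted over the list alone or over all genes; 4 P450 and 5 clock genes were lower and 1 P450 gene was higher at an unadjusted p below 0.05, and DESeq2 called 2 of each. Camera's adjusted p was 2.1e-05 and 0.00058. Both were 0.56 with an estimated correlation. Without TG replicate 3, 9 P450 and 11 clock genes fell and 1 P450 gene rose when adjusted over the list alone. The same count was 6 P450 genes without WT replicate 3 and 1 clock gene without WT replicate 1. The time of day of collection was not given in the labels.

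Genes of the respiratory chain and of the ribosome were lower by small amounts in TG livers. All 41 oxidative phosphorylation genes had a negative fold change, with a median of -0.43, and all 70 ribosomal protein genes did, with a median of -0.32. Examples were Ndufb8 at 34.4 ± 6.06 against 52.5 ± 12.1 CPM, Sdhb at 131 ± 13.2 against 187 ± 28.2 and Rpl21 at 39.96 ± 3.44 against 55.3 ± 13.2. The 12 mitochondrially encoded genes had a median of -0.58, and 33 genes of the TCA cycle -0.29. With edgeR, 0 members of these lists passed when adjusted over the list alone or over all genes, and DESeq2 called 0; at an unadjusted p below 0.05, 5, 1, 2 and 2 members were lower. When adjusted over the list alone, 1 mitochondrially encoded gene fell without TG replicate 3. Mitochondrial genes have nuclear copies, and ribosomal protein genes have pseudogenes, so single values are uncertain. In TG livers mt-Co1, named after its values were seen, lay at 15100 CPM, against 20.9 CPM for mt-Co3. If reads were dropped in counting, the median of the mitochondrially encoded list is uncertain too. Camera's adjusted p was 8.6e-14, 8.6e-14, 7.7e-05 and 7.7e-05. It was 0.56, 0.57, 0.56 and 0.56 with an estimated correlation. With library size only, the medians of the first 2 lists were -0.28 and -0.19, against 0.09 for all genes. By library, the groups overlapped for mitochondrially encoded genes (-0.42, -0.77 and -0.40 in TG replicates 1 to 3, 0.27, 0.12 and -0.43 in WT replicates 1 to 3). They also overlapped for the TCA cycle (-0.16, -0.53 and -0.31 against 0.01, 0.24 and -0.26).

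**Figure D4:**
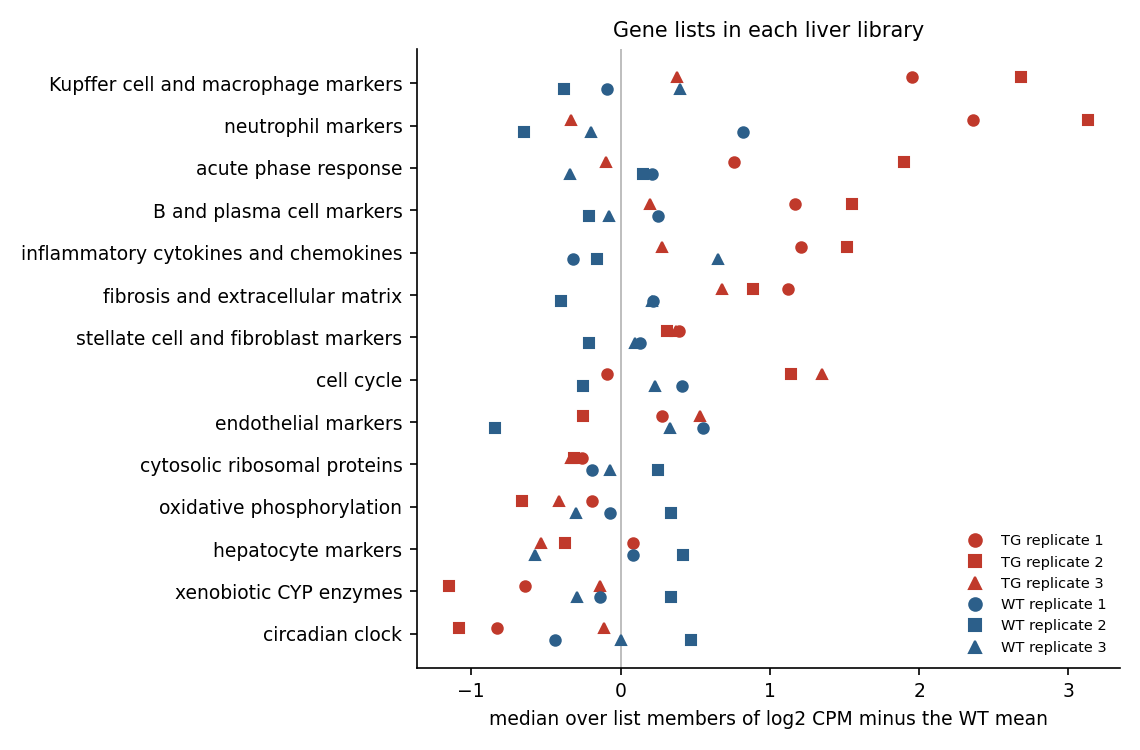
Median over the members of 14 gene lists of log2 CPM minus the WT mean, for each of the 3 TG and 3 WT livers. Macrophage markers reach 1.95 and 2.68 in TG replicates 1 and 2 and 0.38 in TG replicate 3, and matrix genes lie between 0.68 and 1.12 in the 3 TG livers.

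Of the lists nearest to the transgene, camera called 1, the amino acid response (adjusted p 0.042). That adjusted p was 0.75 with an estimated correlation and 0.15 without Slc7a11 in the list. Slc3a2, the partner subunit of Slc7a11 in the exchanger, lay at 207, 153 and 240 CPM in TG replicates 1 to 3 and at 29.5, 34.4 and 98.7 CPM in WT replicates 1 to 3. Its adjusted p was 0.343 with edgeR and Benjamini-Hochberg adjustment and 0.0105 with DESeq2. Gclc and Gclm, the subunits of the first enzyme of glutathione synthesis, lay at 345 ± 166 against 323 ± 115 CPM and at 222 ± 53.7 against 244 ± 51.2 CPM. Gpx4, which reduces lipid peroxides, lay at 251 ± 23.8 against 259 ± 16.9 CPM, and Nqo1 at 14.7 ± 6.32 against 15.3 ± 4.49. Hmox1, a heme oxygenase, lay at 98.3, 354 and 35.8 CPM in TG replicates 1 to 3 and 17.6 to 26.1 CPM in WT. The median log2 fold change was -0.09 for 26 glutathione genes, 0.00 for 38 NRF2 targets, -0.07 for 31 ferroptosis genes and -0.17 for 27 genes of the unfolded protein response, and camera called none of these lists (adjusted p 0.70, 0.70, 0.69 and 0.29). With edgeR, 1 glutathione gene and 1 NRF2 target, in both cases Slc7a11, rose when adjusted over the list alone, and 0 did over all genes; DESeq2 called 3 and 2 higher. Without TG replicate 3, 3 glutathione genes and 3 NRF2 targets rose and 1 and 3 fell, and without WT replicate 3, 3 and 2 rose. Camera called the NRF2 list lower without TG replicate 3 (adjusted p 0.046) and higher without WT replicate 3 (0.028), and the unfolded protein response lower without TG replicate 3 (0.0097) or WT replicate 1 (0.00014). Fry's mixed test, which asks only for change in either direction, gave the glutathione list an adjusted p of 0.028, with Slc7a11 a member. The 33 amino acid response genes had a median of -0.09 and a mean of 0.34, a difference in sign; on the voom values that camera uses the median was 0.19. Camera's call of this list also ended without TG replicate 3 (0.44) or WT replicate 2 (0.28), and without WT replicate 1 the list lay lower (0.88). It ended with library size only too (0.12). Slc7a11 was the 1 member that rose when adjusted over the list alone, and 10 did without WT replicate 3; DESeq2 called 2 over all genes.

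Camera called neither the list of energy sensing genes nor that of mitochondrial turnover with all libraries. Prkaa1 and Prkaa2, the catalytic subunits of AMP-activated kinase, lay at 21.1 ± 2.16 against 16.7 ± 3.57 CPM and at 75.2 ± 15.4 against 103 ± 19.2 CPM. Pink1 lay at 156 ± 34.6 against 192 ± 50.4 CPM, Bnip3 at 82.2 ± 16.9 against 130 ± 63.9, Sqstm1 at 875 ± 265 against 686 ± 385 and Map1lc3b at 138 ± 31.5 against 147 ± 47.9. The AMPK list had a median of -0.03 (camera adjusted p 0.31) and the autophagy and mitophagy list -0.09 (0.21), the latter called lower without TG replicate 1 (0.038) or WT replicate 3 (0.016). With edgeR, 0 members of either list passed when adjusted over the list alone or over all genes. DESeq2 called 2 AMPK genes lower over all genes and 0 of the other list. Over the list alone, 2 AMPK genes fell in edgeR with DESeq2 size factors and 1 with no filter on low counts. Of the lipid genes, Fasn lay at 87.0, 172 and 241 CPM in TG replicates 1 to 3 and at 48.45, 89.3 and 2304 CPM in WT replicates 1 to 3, so that its log2 fold change was -2.29 (SE 1.34) with all libraries and 1.28 without WT replicate 3. Scd1 lay at 1074 ± 568 against 1760 ± 1340 CPM and Cpt1a at 1013 ± 337 against 926 ± 425. The 24 lipogenesis genes had a median of -0.52 (camera adjusted p 0.0057), a call that ended without WT replicate 3 (0.37). It was 0.56 with an estimated correlation. With edgeR, 0 of these genes passed when adjusted over the list alone or over all genes, 4 were lower at an unadjusted p below 0.05, and DESeq2 called 0.

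Of the remaining lists, those for MHC class II (median 1.03), cell cycle (0.66), dendritic cells (0.61), T and NK cells (0.52), immediate early genes (0.39), p53 targets and cell death (0.38) and interferon response (0.26) lay higher in TG by camera. Their adjusted p was between 0.56 and 0.67 with an estimated correlation. By library the cell cycle median was -0.09, 1.14 and 1.35 in TG replicates 1 to 3 and 0.41, -0.25 and 0.23 in WT replicates 1 to 3, and that of MHC class II 1.58, 0.99 and -0.08 against 0.00, -0.29 and 0.28. Mki67 lay at 13.4, 37.5 and 24.8 CPM in TG replicates 1 to 3 and at 13.5, 4.77 and 9.0 CPM in WT replicates 1 to 3. Cdkn1a, a cell cycle inhibitor, lay at 74.8 ± 25.1 CPM against 21.7 ± 11.2. Ripk3, a kinase of necroptosis, was the 1 member of the p53 and cell death list that rose when adjusted over the list alone. That count was 0 without TG replicate 1, TG replicate 2, WT replicate 1 or WT replicate 2, 3 without TG replicate 3 and 8 without WT replicate 3. It was also 0 with voom, with a fold threshold of 1.2 and at a mean of at least 1 CPM. The lists for methionine cycle and transsulfuration (-0.30), PPARA targets (-0.33), hepatocyte markers (-0.37) and female-biased genes (-0.86) lay lower. Their adjusted p was between 0.56 and 0.71 with an estimated correlation, where 0.56 was the smallest of any list. WT replicate 3 was the lowest liver for PPARA targets (-0.70, against 0.17, -0.60 and -0.55 in TG replicates 1 to 3) and for hepatocyte markers (-0.57, against 0.08, -0.37 and -0.53). It was also the lowest for the methionine cycle list (-0.39, against -0.13, -0.33 and -0.30). Beside Ripk3, 0 members of these lists passed when adjusted over the list alone, with 7 cell cycle and 6 MHC class II genes higher at an unadjusted p below 0.05 and 3 and 1 called by DESeq2. Without TG replicate 3, 11 MHC class II genes and 1 each of the dendritic, methionine cycle and hepatocyte lists rose, and of the female-biased genes 2 rose and 4 fell; without WT replicate 3, 2 immediate early genes rose. Camera calls ended for dendritic cells without TG replicate 1 (adjusted p 0.057) or WT replicate 3 (0.065), and for immediate early genes without WT replicate 1 (1). For T and NK cells they ended without TG replicate 1 (0.36), TG replicate 2 (0.063), WT replicate 2 (0.34) or WT replicate 3 (0.17), as well as with library size only (0.1) and at a mean of at least 1 CPM (0.078). For interferon response they ended without TG replicate 2 (0.093) or WT replicate 1 (0.75). For the methionine cycle they ended without TG replicate 3 (0.083), WT replicate 1 (0.15) or WT replicate 2 (0.095), and for PPARA targets without TG replicate 2 (0.071) or WT replicate 2 (0.33). For hepatocyte markers they ended without TG replicate 2 (0.069), TG replicate 3 (0.32), WT replicate 1 (0.17) or WT replicate 2 (0.72), and for female-biased genes without TG replicate 2 (0.22), TG replicate 3 (0.12), WT replicate 2 (0.089) or WT replicate 3 (0.13). In all, leaving out 1 library ended the call of 11 of the 27 called lists and kept that of 16. Alb lay at 71910 ± 3990 CPM in TG and 103000 ± 31400 in WT.

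Lists for cholesterol synthesis (median 0.15), lipid droplets and lipoproteins (-0.15), complement and coagulation (0.01), male-biased genes (-0.07), heat shock (-0.04), pericentral (-0.26) and periportal hepatocytes (-0.37), endothelium (0.11), cholangiocytes (0.16), erythroid cells (-0.08) and adipocytes and mesothelium (-0.02) were not called by camera (adjusted p between 0.077 and 0.74). DESeq2 called 2 male-biased genes and 1 each of the complement, heat shock and cholangiocyte lists higher over all genes. With all libraries and a mean of at least 1 CPM, camera called the cholangiocyte list higher (adjusted p 0.039). Leaving out 1 library gave a call for 7 of these lists, beside the NRF2, unfolded protein response and autophagy lists given above. Endothelial markers were called higher without TG replicate 2 (0.00063), WT replicate 1 (0.00052) or WT replicate 3 (0.022), cholesterol synthesis higher without WT replicate 2 (0.03) or WT replicate 3 (0.00071), and cholangiocytes higher without TG replicate 1 (0.045). Periportal markers were called lower without TG replicate 1 (0.041) or WT replicate 3 (1e-05), lipid droplets lower without TG replicate 1 (0.038), heat shock lower without WT replicate 1 (0.011) and male-biased genes higher without WT replicate 1 (0.033). Too few pancreatic acinar and skeletal muscle markers passed the filter on low counts for a test, 1 and 2 genes. At a mean of at least 1 CPM, enough skeletal muscle markers remained, and they lay lower in TG without a call (camera adjusted p 0.053). Ptgs2, Timp1, Tnf and Il6 were removed as low in counts. Timp1 had 12, 38 and 10 counts in TG replicates 1 to 3 and 3, 4 and 8 in WT replicates 1 to 3, and Ptgs2 had 1, 9 and 2 against 0 in each WT library.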

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

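Leaving out replicate 3 of both groups, other scalings for the lists and all alternatives for members adjusted over the list alone were chosen after the data were seen. The cause was not tested for any change below. Over genes, edgeR called 0 with other scalings, filters, dispersion, fold threshold, an adjusted p of 0.1, the replicate block, and without the 10 genes of highest count. DESeq2 gave 390 genes, 17 matrix members and a log2 fold change of 8.99 for Slc7a11, and voom gave 1 gene, 15 macrophage members, 9.04 for Slc7a11 and 0.01 for Chac1. Slc7a11 was past the threshold in both. Without replicate 3 of both groups, edgeR gave 437 genes, 2421 at an unadjusted p below 0.05, 18 matrix members and 9.84 for Slc7a11 (adjusted p 0.0144 by edgeR and Benjamini-Hochberg, over all alternatives 3.19e-51 to 0.697). The matrix members numbered 14 with no filter on low counts and 18 at an adjusted p below 0.1. The replicate block left 6 macrophage and 0 matrix members and 0.01 for Chac1, and ended the amino acid response call (camera adjusted p 0.14). Deviations of same-numbered libraries correlated across genes by 0.15, -0.22 and 0.10, and those of other TG and WT pairs by -0.26 to 0.14. With 3 libraries per group, such values cannot show whether the numbers pair the mice. An estimated inter-gene correlation left 0 gene lists and fry left 0, and other settings gave 22 to 28 of them.

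With 1 library left out, the ranges were 0 to 305 genes, 759 to 2328 at an unadjusted p below 0.05, 1 to 28 macrophage members, 0 to 16 matrix members and 8.57 to 9.85 for Slc7a11. Signs turned for genes that were not past the threshold. With library size only, Gclm was 0.03, Map1lc3b 0.07, Gpx4 0.08 and Nqo1 0.06. Without replicate 3 of both groups, Fasn was 0.90, Acta2 -0.17, Chac1 0.51, Cpt1a -0.02 and Gclc -0.08. With 1 library left out, Acsl4 lay between -0.15 and 0.72, Acta2 between -0.07 and 0.90, Chac1 between -1.12 and 0.73, Cpt1a between -0.20 and 0.47, Fasn between -2.85 and 1.28, Gclc between -0.39 and 0.40, Gclm between -0.32 and 0.05, Gpx4 between -0.14 and 0.03, Map1lc3b between -0.34 and 0.09 and Nqo1 between -0.50 and 0.22. The adjusted p of camera for the amino acid response list (ATF4) lay between 9.5e-08 and 0.88, and without WT replicate 1 (0.88) its direction turned. Of 131 other named genes, 49 were past the threshold with DESeq2 and 27 without TG replicate 3. Depth limits genes below 0.172 to 0.187 CPM.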

Other observations

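The tests of hepatocyte share, blood, scaling, a swap, dilution, depth and the count over splits of genes past adjusted p 0.05 were chosen only after the result was seen, while those of transcript length, GC content, lysosomal genes and the other counts over splits were set before theirs. Genes in the next 2 paragraphs, and Prtn3, Ctsg, Arl8a and Dpp7 further below, were chosen after their values were seen, except those named in the comparison.

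Transcripts of immature granulocytes were abundant in TG replicates 1 and 2 and at or near 0 counts in the other libraries. Mpo, the myeloperoxidase of azurophil granules, had 251 and 1216 counts in TG replicates 1 and 2, 1 count in TG replicate 3 and 0 in each WT library. Elane had 155, 731 and 0 counts in TG replicates 1 to 3 and at most 2 in a WT library. Ngp, of later granules, had 573, 579 and 0 counts against at most 7. Meg3 lay at 13.7, 12.5 and 1.52 CPM in TG replicates 1 to 3 and 0.728 to 1.40 CPM in WT, and Igf2 at 18.3, 7.23 and 0.457 CPM against 0.303 to 0.698 CPM. The clock genes Per3 and Ciart lay at 6.80, 7.06 and 35.0 CPM and at 1.58, 1.02 and 17.0 CPM in TG replicates 1 to 3, against WT ranges of 35.9 to 70.8 and 14.6 to 28.2 CPM.

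Other genes lay beyond all 3 WT livers in all 3 TG livers, TG replicate 3 included. Slc37a4, the glucose-6-phosphate transporter that works with G6pc, lay at 117, 132 and 162 CPM against 253 to 309 CPM in WT. Cldn4, a tight junction protein, lay at 6.80, 1.47 and 8.94 CPM against 0.127 to 0.572, and it was the 1 cholangiocyte marker past the threshold when adjusted over the list alone (0 over all genes with edgeR). That call ended without TG replicate 1, WT replicate 1 or WT replicate 2, each of which left 0, and with voom, and the count was 2 higher and 1 lower without TG replicate 3. Ucp2, a mitochondrial carrier, lay at 123, 157 and 54.2 CPM against 27.2 to 29.6 CPM. The adjusted p of these 3 genes was 0.343 with edgeR and Benjamini-Hochberg adjustment and 0.00171, 0.000274 and 0.000433 with DESeq2.

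Macrophage markers were higher in TG livers, and explanations other than more macrophage RNA were weighed. A lower share of hepatocytes would raise the markers of every other cell type alike, but the macrophage median exceeded the endothelial median by 1.80 (95% bootstrap interval over genes 1.54 to 2.07); by library this difference was 1.67, 2.93 and -0.15 in TG replicates 1 to 3 and -0.64, 0.46 and 0.07 in WT replicates 1 to 3, so it argues against this in TG replicates 1 and 2 and not in TG replicate 3. Blood left in the liver would raise globin, whose summed log2 CPM differed by -0.03 ± 1.46 (SE of the difference of means) between groups, at 23.0, 31.9 and 2.49 CPM in TG replicates 1 to 3 and 19.5, 27.1 and 3.69 CPM in WT replicates 1 to 3. With so wide an SE, the group difference cannot decide on blood. WT replicates 1 and 2, with globin near that of TG replicates 1 and 2, had macrophage medians of -0.09 and -0.38. Other scalings left a median of at least 1.90, so scaling does not account for it. Whether more cells, more RNA per cell or a condition of TG replicates 1 and 2 other than the transgene lies behind it stays open and was not tested.

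TG replicate 3 was closest to WT replicate 3 (r = 0.973 across genes, which are not independent replicates) and lay between the other TG livers and the WT livers on the first principal component; these 2 livers also had the lowest globin. A swap with a WT library is argued against by its Slc7a11 level, 274 times the highest WT library. RNA of TG replicate 1 diluted with WT RNA would carry Mpo, Elane, Prtn3 and Ctsg along, but their sum was 0.00377 times the level set by Slc7a11, from 2 counts. Depth is no explanation, since its total of 17.1 M counts lies within the range of the other libraries, 16016640 to 17463329. An infection or injury of the mice of TG replicates 1 and 2, litter, and a different hour of collection stay open; the labels give none of them, so they were not tested.

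Ribosomal protein and oxidative phosphorylation genes were lower in TG livers by a median of -0.35 over 111 genes. Removing the trend with transcript length fitted on the other genes left -0.34 (95% bootstrap interval over genes -0.38 to -0.32). Removing that with GC content left -0.44 (-0.46 to -0.42). These intervals resample genes that vary together, so they do not measure the spread between mice. Over the scalings the median lay between -0.36 and -0.21, while that of all genes moved by at most 0.12. These values argue against length, GC content or scaling as the whole cause. With TMM scaling, the medians by library overlap for oxidative phosphorylation (-0.19, -0.66 and -0.41 in TG replicates 1 to 3, -0.07, 0.34 and -0.30 in WT replicates 1 to 3) but not for ribosomal proteins (-0.26, -0.31 and -0.33 against -0.19, 0.25 and -0.07). As a share of raw counts, ribosomal protein genes overlapped too, at 1.3, 1.28 and 1.46% in TG replicates 1 to 3 and 1.32, 1.55 and 1.74% in WT replicates 1 to 3. A shift between cell types was not excluded.

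A hypothesis was that lysosomal genes rise together in TG livers, since Cd63, Gpnmb, Rragd, Arl8a and Dpp7 were high in all 3 of them. A list of 40 other lysosomal genes, 4 of which are in the autophagy list, had a median log2 fold change of 0.28 and 33 members above 0. Camera gave it p = 4.2e-06 with the preset correlation and p = 0.18 with an estimated correlation, and 0 members passed when adjusted over the list alone with edgeR. Its median against the WT mean was 0.37, 0.36 and 0.19 in TG replicates 1 to 3 and -0.06, 0.21 and -0.18 in WT replicates 1 to 3. The hypothesis stays open, and macrophages, which are rich in lysosomes, could account for the values as well.

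The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. For edgeR's 0 genes past adjusted p 0.05 the count over splits tests nothing, since all 10 reach 0 by construction; the highest other count was 2. The 1551 genes at an unadjusted p below 0.05 were reached by 2 splits, the highest other count being 1592, in the split that sets TG replicate 1 with WT replicates 1 and 2, which points to a structure of the samples other than the groups. The 27 gene lists were reached by 1 split, the real one, with 26 the highest other count. Every other split called at least 11 lists, so camera with the preset correlation finds lists in any grouping of these libraries. The 28 macrophage markers were reached by 1 split, with 23 the highest other count, in the split that sets TG replicates 1 and 2 with WT replicate 3.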
